A study of Mus musculus with 12 samples.

How the data were processed

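RNA was measured on 12 Affymetrix mouse arrays, 3 for each of 4 genotypes of a CRISPR/Cas9-edited murine Burkitt lymphoma cell line. Per the labels' protocols, total RNA was purified with a Qiagen kit, converted to cDNA with an Affymetrix 3' IVT kit and labelled with biotin. The deposited values are log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes, with no version given. RMA corrects background, normalizes across arrays and summarises probes, so a shift shared by most genes of an array is largely removed before these values. The base of the logarithm was taken from the usual output of RMA and from the range of the values, 3.09 to 15.57. Scanner files were not used here.

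Probe sets were named through GEO's platform annotation, with symbols checked against a RefSeq table of the mouse assembly GRCm38.p6, which was used only for names and for which genes share a chromosome. Of 45101 probe sets, 34958 had 1 gene, 932 had several and were not named, and 9211 were not named in the table. They covered 18195 genes, of which 204 symbols were kept as the array lists them. Each gene was represented by its probe set with the highest mean, and genes were kept when that probe set lay above the array's median in at least 3 arrays, which left 11458. Probe sets of 1 gene can disagree, so a change is that of 1 probe set, and the text gives the range over the brighter probe sets for part of the named genes.

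Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per genotype over all 12 arrays, then eBayes), and called at a Benjamini-Hochberg adjusted p under 0.05 over all kept genes. Errors of log2 changes are limma's standard errors (SE), and errors of levels are SD over 3 arrays. The comparisons were the loss of both alleles, the loss of each allele with the other present or absent, the mutant allele alone against the wild-type allele alone, an F test over the 4 genotypes, and the interaction of both losses. Genotypes came from the labels, and their array numbers run on without a number shared between genotypes, so nothing pairs the arrays. Correlations of changes were taken across genes, which are not independent replicates. For the overlap of comparisons that share wt-/mt-, 100 sets were simulated with both mt- genotypes at the wt-/mt- means and noise drawn from each genotype's own residuals, which keeps the correlations between genes.

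Before the data were examined, 32 gene lists with 684 entries were fixed, and 630 entries matched a gene on the array. They covered canonical FOXO target genes, Foxo1 target genes of lymphocytes, forkhead family members, germinal center dark zone, light zone and identity, B cell identity, early B cells, plasma cells, B cell receptor and PI3K signalling, mTORC1 with lysosome and autophagy, G2/M, S phase, CDK inhibitors and G1, MYC with ribosome biogenesis, amino acid stress, cholesterol synthesis, glycolysis, oxidative phosphorylation, the BCL2 family, p53 targets, somatic hypermutation, class switching and DNA repair, antigen presentation, interferon response, NF-kB targets, trafficking and adhesion, immediate early and heat shock genes, and markers of T cells, NK cells, myeloid, stromal and erythroid cells. The 29 lists with at least 5 kept members were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry as alternatives. No list call of any comparison held with an estimated correlation. Signs of the median, the mean and the test differed for 4 of 29 lists after loss of both alleles, and for between 2 and 8 lists in the other comparisons, and 0 of these lists were called. No called list changed the sign of its median under 3 other scalings, although some calls ended under them, as given with each comparison.

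Named genes followed a rule fixed in advance: Foxo1, up to 10 rises and 10 falls with the largest change among called genes whose 3 arrays of 1 genotype all lay above the 3 of the other (for the interaction, called genes), and up to 4 called members of each list by size of change.

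The fit was tested on simulated arrays with 200 genes of 11458 changed and with the spread of each genotype as in the real arrays. Noise was drawn independently for each gene, unlike that of real arrays. For the loss of both alleles, 37.3% of genes changed by 0.5 (log2), 91.0% of those changed by 1 and 98.5% of those changed by 2 were recovered. The shared estimate of the spread called 151 of the 200 changed and 87 unchanged genes for the loss of both alleles, 156 and 118 for the loss of the wild-type allele without the mutant allele, and 147 and 69 for the loss of the mutant allele without the wild-type allele. It called 139 changed and 1 unchanged gene for the loss of the mutant allele, 141 and 0 for the loss of the wild-type allele, 149 and 1 for the mutant against the wild-type allele alone, and 113 and 11 for the interaction. With 1 weight per genotype, unchanged calls numbered 10, 9 and 2 in the first 3 of these comparisons. Changed calls there fell to 129, 128 and 124, so lower counts in that fit also reflect lost power. In the next 3, changed calls numbered 170, 188 and 170, and unchanged calls 8, 8 and 5. Calls that involve wt-/mt- are therefore too many, and calls among the other genotypes too few, under the shared estimate. For that reason counts of called genes, and of called members of the lists, are also given with 1 weight per genotype. Because noise is shared by genes in real arrays, unchanged calls there may be more numerous than in these simulations, also with 1 weight per genotype. In the sets with correlated noise and no difference between the mt- genotypes, calls shared by the 2 comparisons had a median of 0. They reached 3611 at most under the shared estimate and 2006 with 1 weight per genotype. The number of arrays limits the precision of every value.

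Alternatives fixed before the data were examined were other filters, other choices of probe set, a second quantile normalization, median-centred arrays, eBayes with trend and robust, arrayWeights, only the 2 genotypes compared in the fit, a minimum change of 1, other list tests and each of the 12 arrays left out. Added after seeing the data were 1 weight per genotype, centring per chromosome, the actin 3' to 5' ratio as a covariate, 2 arrays of wt+/mt- left out together, and the wt-/mt- arrays left out of the fit. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.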

Results

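Gene expression was measured in BL#19, a murine Burkitt lymphoma (BL) cell line edited with CRISPR/Cas9. Foxo1 is a forkhead transcription factor that phosphorylation by AKT removes from the nucleus. The line carried a wild-type allele (wt) and an allele with the substitution T24P (mt), which changes a residue phosphorylated by AKT. The 4 genotypes held both alleles (wt+/mt+), the mutant allele alone (wt-/mt+), the wild-type allele alone (wt+/mt-) or neither (wt-/mt-), with 3 arrays each. Most labels name the lymphoma line, and 1 field describes the samples as germinal center B cells. The labels do not say whether the arrays of a genotype came from separate clones or cultures, so p-values measure only the spread between these arrays, which may be technical, and a clone may stand for a genotype. In wt-/mt-, medians of whole chromosomes differed between the arrays, as given at the end, which argues against a purely technical spread in that genotype. Array medians lay between 6.08 and 6.25 (log2), and 0 pairs of arrays were identical.

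The Foxo1 transcript was read first, since it bears on the labels. Its level was 11.64 ± 0.08 (log2, SD, n = 3) in wt+/mt+, 11.46 ± 0.26 in wt-/mt+, 11.87 ± 0.26 in wt+/mt- and 9.99 ± 0.52 in wt-/mt-. After loss of both alleles it fell by 1.65 (SE 0.23, limma adjusted p = 0.00122). It also fell by 1.88 after loss of the wild-type allele without the mutant allele (SE 0.23, adjusted p = 0.000886) and by 1.47 after loss of the mutant allele without the wild-type allele (SE 0.23, adjusted p = 0.00199). Loss of the mutant allele alone gave a change of 0.24 (SE 0.23, adjusted p = 0.736), and loss of the wild-type allele alone one of -0.18 (SE 0.23, adjusted p = 1.00). The interaction was -1.71 (SE 0.32, adjusted p = 0.0226), a call that ended without any 1 of 7 arrays (wt+/mt+ replicates 1, 2 or 3, wt-/mt+ replicates 1 or 3, and wt+/mt- replicates 1 or 2), where it lay between -1.75 and -1.59. Another bright probe set gave -1.65 for it (SE 0.42, adjusted p = 0.105), not called. Another 3 probe sets were read, of which 1 dim set, at 5.47 in wt+/mt+ and 5.73 in wt-/mt-, went the other way (0.26). A probe set outside an edited part does not check the edit, and the position of the edits was not given in the sources used here, so these levels check the labels of wt-/mt- only in part and those of single losses not at all. Without wt+/mt- replicates 1 and 2, whose actin ratios were highest, Foxo1 without the mutant allele fell by 1.60 on the log2 scale and no longer called, and the interaction was -1.43 and not called.

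**Figure D1:**
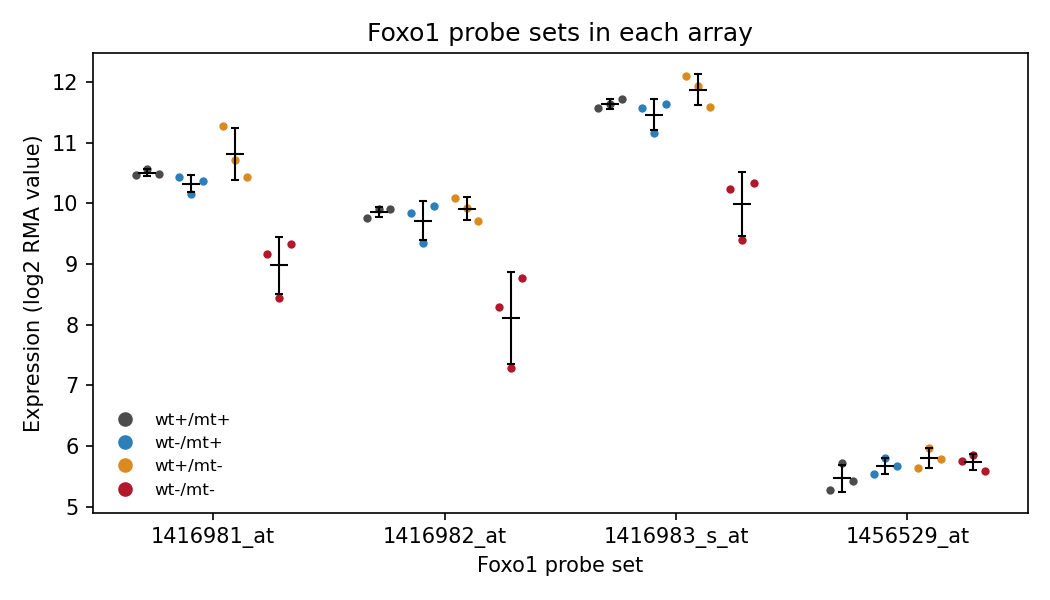
Level (log2 RMA value) of the 4 Foxo1 probe sets on each array, coloured by genotype, with points for arrays and bars for the mean ± SD of 3 arrays. The probe set used in the tests had a mean of 9.99 in wt-/mt- and means between 11.46 and 11.87 in the other genotypes, and the dim set had means of 5.73 in wt-/mt- and 5.47 in wt+/mt+.

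Over the 4 genotypes, the F test called 2202 genes of 11458 (limma), with 4138 at an unadjusted p under 0.05. Without wt+/mt+ replicates 2 or 3, wt-/mt+ replicate 2 or wt+/mt- replicate 2, the counts were 1296, 1340, 1383 and 1369. The first principal component held 43.4% of the variance, with the 3 wt-/mt- arrays between 34.8 and 50.8 and the other 9 between -19.4 and -5.74. The arrays of wt-/mt- also differed more from one another. The median SD over genes was 0.261 there, against 0.0952 in wt+/mt+, 0.111 in wt-/mt+ and 0.133 in wt+/mt-. The spiked hybridisation transcripts bioC, bioD and cre were lower on the 6 mt- arrays than on the 6 mt+ arrays, by differences of -0.71, -0.83 and -0.40 (exact permutation p = 0.00216 for each, counting both directions, adjusted p = 0.00433 over 8 measures), while the fourth, bioB, did not pass the test (-0.026, exact permutation p = 0.805). The spiked labelling transcripts lys and phe were higher on the mt- arrays, by 1.22 and 0.80 (exact permutation adjusted p = 0.00433 and 0.0173), and dap, at 0.74, did not pass (adjusted p = 0.0808). The actin 3' to 5' ratio was 2.17 and 1.71 (log2) in wt+/mt- replicates 1 and 2, and between 1.06 and 1.29 in the other 10 arrays.

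Loss of both alleles raised Anxa10, an annexin, by 5.18 (log2 change, SE 0.60, n = 3 arrays per genotype, limma adjusted p = 0.000386), from 7.31 ± 0.29 to 12.49 ± 1.53. Havcr1, a T cell immunoglobulin and mucin domain receptor, rose by 3.90 (SE 0.35, adjusted p = 7.63e-05). Mpeg1, a pore-forming protein of phagocytes, rose by 3.76 (SE 0.64). So did Cybb, the catalytic subunit of the phagocyte NADPH oxidase, by 3.66 (SE 0.37), and Ncf4, another subunit of that oxidase, by 2.66 (SE 0.48). Lgals1, which encodes galectin-1, rose by 3.46 (SE 0.91), and Klhl6, an adaptor of ubiquitin ligases in B cells, by 3.35 (SE 0.46). Clec2i rose by 2.83, Tnni2 by 2.80 and Slc11a1 by 2.63. The largest falls were of Dnaic2 (-5.81, SE 0.74), Ehf, an ETS factor (-5.30, SE 0.34), Zfyve28 (-5.08, SE 0.51) and Wfdc21 (-4.95, SE 0.60). Csf1, the macrophage growth factor, fell by 4.55 (SE 0.30), although its 4 probe sets ranged from -4.55 to 0.15. Bach2, a repressor of plasma cell differentiation, fell by 4.41 (SE 0.45, adjusted p = 0.000201), and Cxcr4, a chemokine receptor, fell by 3.69 (SE 0.42, adjusted p = 0.000346). Lct fell by 4.01, Gm8369 by 3.91 and Matn1 by 3.67 (SE 1.07). In all, 2535 genes were called, 1396 higher and 1139 lower, with 4381 at an unadjusted p under 0.05 and 2482 of the called genes without overlap between the arrays. Called genes were chosen by a test on these same arrays. Their separation, here and in the other comparisons, therefore follows largely from the choice and adds no support. With each array centred on its median, 2355 were called, 880 higher and 1475 lower. Under 1 weight per genotype, 866 were called, 316 higher and 550 lower, 860 of them among the 2535, and the calls of Slc11a1 and Matn1 ended. The probe sets of Cybb ranged from 1.80 to 3.66 and those of Bach2 from -4.49 to -0.84. Without wt+/mt+ replicates 1, 2 or 3 in turn, 1485, 1251 and 1302 genes were called.

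**Figure D2:**
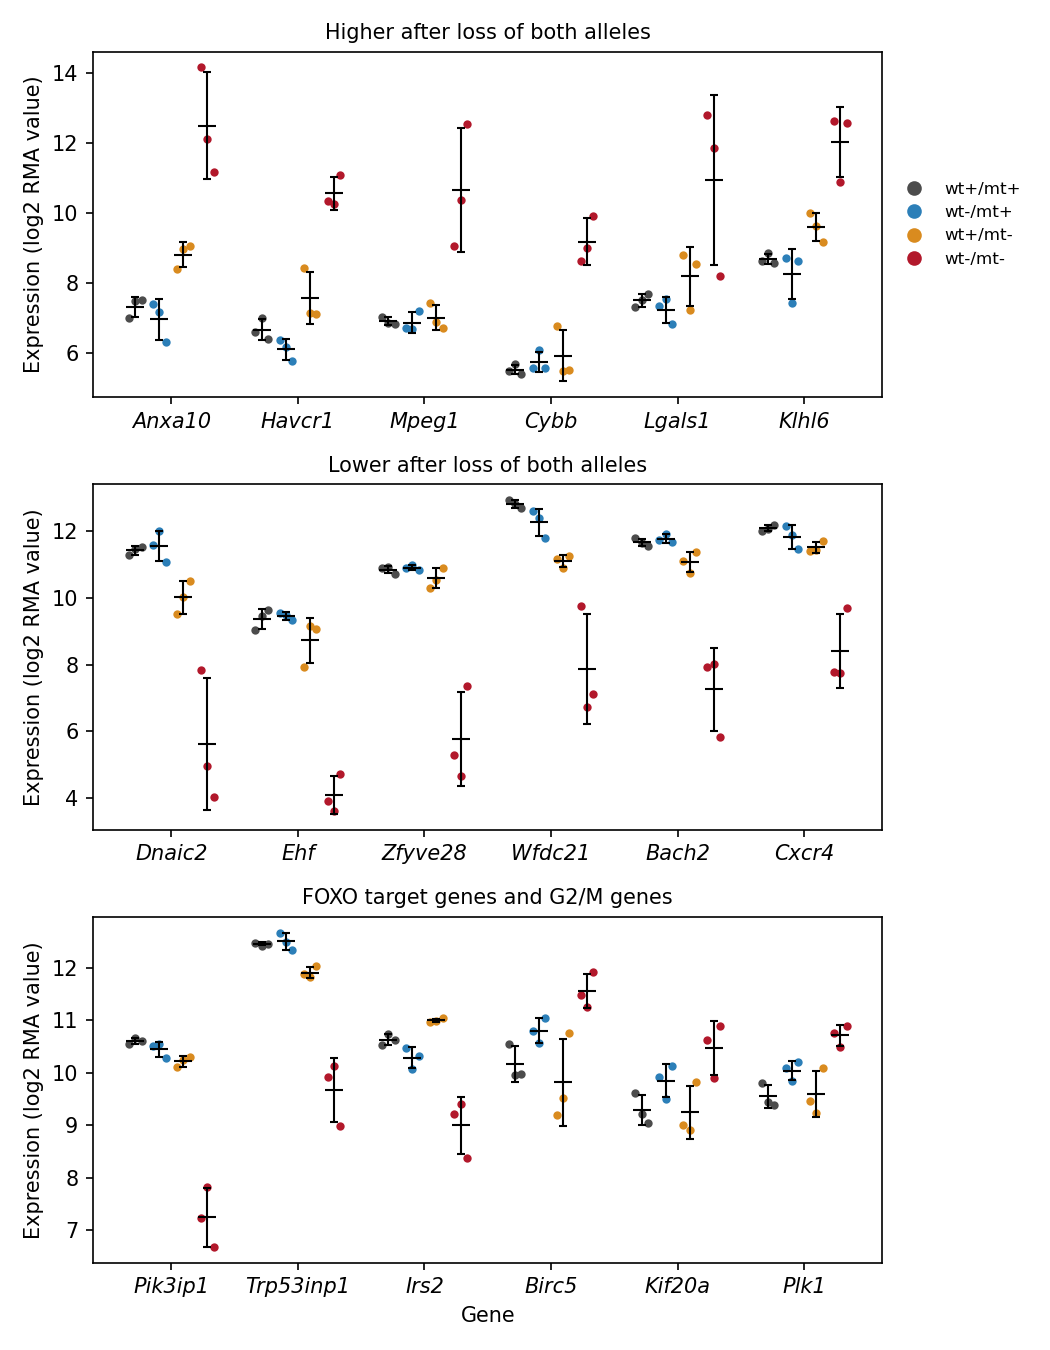
Level (log2 RMA value) of 18 named genes on each array, coloured by genotype, with points for arrays and bars for the mean ± SD of 3 arrays. Anxa10 went from 7.31 in wt+/mt+ to 12.49 in wt-/mt-, and Bach2 from 11.67 to 7.26.

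Among canonical FOXO target genes, 17 of 31 fell after loss of both alleles and 0 rose, and 19 fell adjusted over the list alone. The median change was -0.58 (camera adjusted p = 9.01e-09, adjusted p = 0.310 with an estimated correlation). The falls were -3.36 (SE 0.22) for Pik3ip1, an inhibitor of PI3K, and -2.78 (SE 0.24) for Trp53inp1, a regulator of autophagy and the p53 response, whose other probe set gave -0.26. Irs2, an insulin receptor substrate, changed by -1.63 (SE 0.22) and Sesn1, a sestrin, by -1.56 (SE 0.39). Of 14 Foxo1 target genes of lymphocytes, 9 fell and 0 rose, and 10 fell adjusted over the list alone (median -1.05, adjusted p = 2.11e-06, adjusted p = 0.263 with an estimated correlation). Bach2, Cxcr4 and Pik3ip1 led this list too, and Btla, an inhibitory receptor, fell by 1.64 (SE 0.46). In the G2/M list 20 of 27 genes rose, 23 adjusted over the list alone, with a median of 0.82 (adjusted p = 4.70e-08, adjusted p = 0.594 with an estimated correlation). Birc5 rose by 1.39 (SE 0.35), Kif20a by 1.18 (SE 0.30), the mitotic kinase Plk1 by 1.16 (SE 0.21) and Ube2c by 1.14 (SE 0.26). In the S phase list 8 of 24 rose, also 8 adjusted over the list alone (median 0.61, adjusted p = 0.000326, adjusted p = 0.594 with an estimated correlation), among them Uhrf1 by 1.44 (SE 0.32), Mcm2 by 1.04 (SE 0.23), E2f1 by 0.99 and Ccne1 by 0.90. With 1 weight per genotype, 1 gene of the G2/M list, 2 of the S phase list, 10 of the canonical list and 6 of the lymphocyte list were called, and the calls of Birc5, Kif20a, Plk1, Ube2c, Uhrf1 and Mcm2 ended.

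In the MYC and ribosome biogenesis list 12 of 33 genes rose after loss of both alleles, with 16 higher and 1 lower adjusted over the list alone (median 0.39, camera adjusted p = 0.000298, adjusted p = 0.594 with an estimated correlation). Tfap4 rose by 0.86 (SE 0.11), Srm by 0.85 (SE 0.26), Rrp12 by 0.74 (SE 0.24) and Mybbp1a by 0.73 (SE 0.11). Of 15 B cell identity genes 7 fell, 8 adjusted over the list alone (median -0.77, adjusted p = 0.000326, adjusted p = 0.472 with an estimated correlation), with the kinase Blk at -1.87 (SE 0.45), Cd72 at -1.08 (SE 0.14) and Cd79b, a chain of the B cell receptor, at -0.96 (SE 0.24). The immunoglobulin heavy chain gene Ighm fell by 1.14 (SE 0.25), while 1 of its 5 probe sets gave 0.51. The mTORC1, lysosome and autophagy list had 5 falls of 23 (adjusted over the list alone, 6 lower and 1 higher, adjusted p = 0.0281), antigen presentation 3 of 20 (3 adjusted over the list alone, adjusted p = 0.0301), and p53 targets 5 falls and 1 rise of 17 (8 and 2 adjusted over the list alone, adjusted p = 0.0459). Each of these 3 had an adjusted p = 0.594 with an estimated correlation. The p53 call ended after quantile normalization, with median-centred arrays and after centring per chromosome, and the antigen presentation call with median-centred arrays. H2-Ob, a chain of the class II chaperone H2-O, fell by 3.02 (SE 0.29), the kinase Ulk1 by 0.91 (SE 0.14) and Plk2 by 1.04 (SE 0.22). In the BCL2 family 5 of 12 fell and 3 rose, with 5 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.561). The pro-apoptotic Bmf fell by 3.10 (SE 0.31) and Bcl2l11, which encodes BIM, by 1.34 (SE 0.25), the anti-apoptotic Mcl1 fell by 1.22 (SE 0.30), and the pro-apoptotic Bid rose by 1.40 (SE 0.12). Probe sets ranged from -3.10 to -0.34 for Bmf, from -1.34 to -0.51 for Bcl2l11, from 0.57 to 1.40 for Bid and from -0.91 to -0.23 for Ulk1. Under 1 weight per genotype 2 MYC and ribosome biogenesis genes rose, 5 B cell identity genes fell, 2 fell in each of the mTORC1 and antigen presentation lists, 1 p53 target fell, and in the BCL2 family 4 fell and 2 rose, and the calls of Srm, Rrp12 and Plk2 ended. In wt-/mt-, which also had the widest spread between arrays and, with wt+/mt-, the lower bioD signal (-0.83), 9 lists were called in all, 3 higher and 6 lower.

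**Figure D3:**
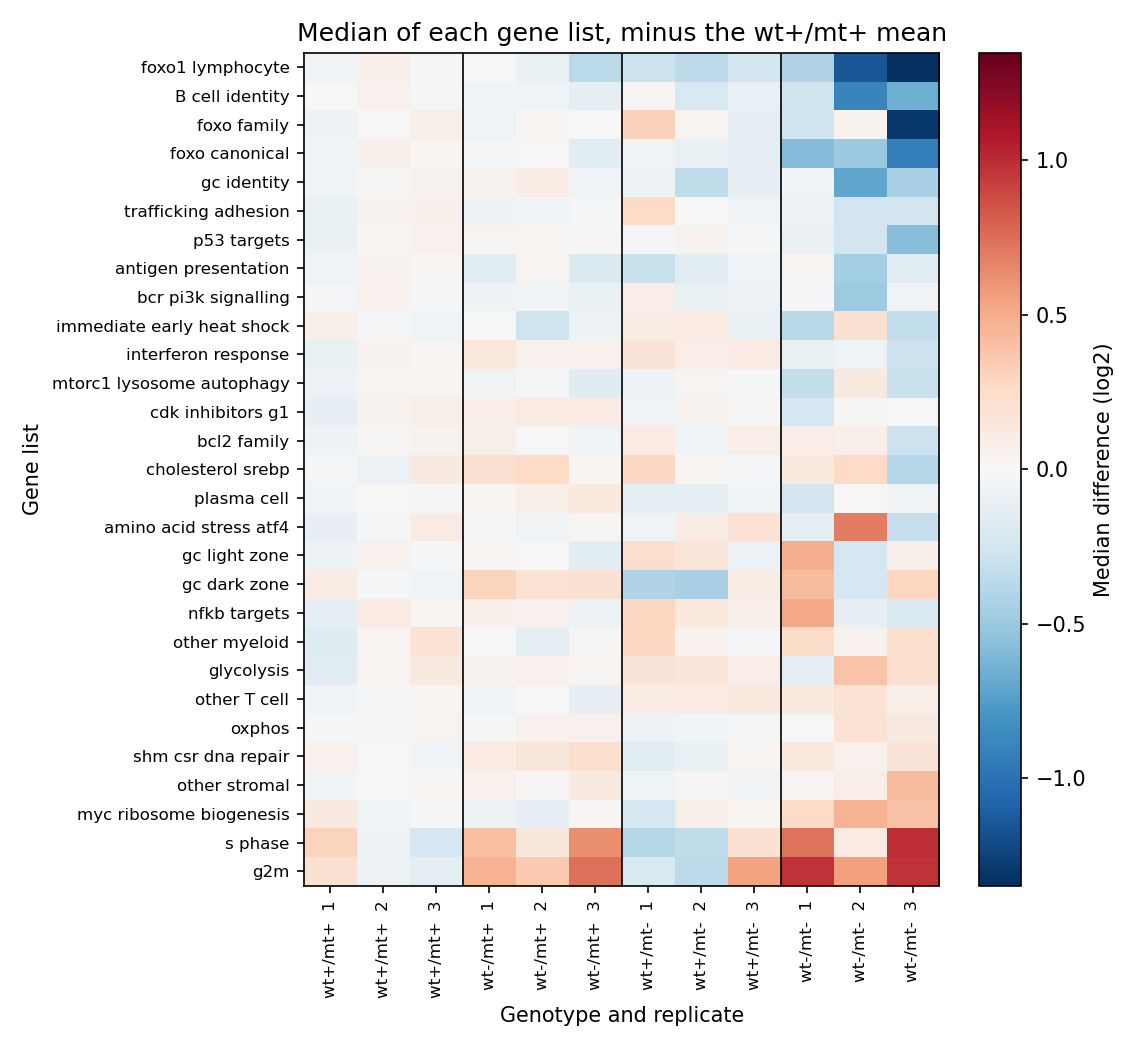
Each of the 29 tested gene lists (vertical) on each of the 12 arrays (horizontal, by genotype and replicate), coloured by the median over its genes of the log2 difference from the wt+/mt+ mean. The G2/M list was at 0.98, 0.55 and 0.98 in wt-/mt- replicates 1, 2 and 3.

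Loss of the wild-type allele in cells without the mutant allele (wt-/mt- against wt+/mt-) raised Clec2i by 3.78 (SE 0.28, n = 3 arrays per genotype, limma adjusted p = 6.20e-05), Anxa10 by 3.69 (SE 0.60), Mpeg1 by 3.66 (SE 0.64), Cybb by 3.27 (SE 0.37), Ncf4 by 3.07 (SE 0.48) and Havcr1 by 3.01 (SE 0.35). Cotl1 rose by 2.65 (SE 0.71), Tnni2 by 2.44 and Klhl6 by 2.43. Falls were found for Matn1 (-5.20, SE 1.07), Cdyl2 (-5.11, SE 0.66), Zfyve28 (-4.83, SE 0.51) and Ehf (-4.65, SE 0.34). Dnaic2 (-4.41), Scamp1 (-4.19, SE 1.13), Bach2 (-3.82) and Nmrk2 (-3.53) fell too. In all 1670 genes were called, 728 higher and 942 lower, with 3458 at an unadjusted p under 0.05 and 1600 called genes without overlap. Of 27 G2/M genes 16 rose, 24 adjusted over the list alone (median 0.86, camera adjusted p = 6.94e-12), and of 24 S phase genes 12 rose, 17 adjusted over the list alone (median 0.93, adjusted p = 1.77e-08). Cdk1 rose by 1.34 (SE 0.30), Birc5 by 1.74 (SE 0.35), Prim1 by 1.21 (SE 0.32) and Mcm5 by 1.16 (SE 0.28). MYC and ribosome biogenesis had 8 rises of 33, 19 adjusted over the list alone (adjusted p = 8.97e-08). Of 31 canonical FOXO targets 14 fell, 16 adjusted over the list alone (adjusted p = 1.48e-06), with Pik3ip1 at -2.97, Trp53inp1 at -2.23 and Irs2 at -2.00, and of 14 lymphocyte targets 6 fell, also 6 adjusted over the list alone (adjusted p = 1.95e-05). Each of these 5 lists had an adjusted p = 0.393 with an estimated correlation. Relative to the wt+/mt+ mean, the G2/M median was -0.20, -0.36 and 0.54 in wt+/mt- replicates 1, 2 and 3 and 0.98, 0.55 and 0.98 in wt-/mt-, and the S phase median was -0.38, -0.34 and 0.21 against 0.73, 0.12 and 0.99. Replicates 1 and 2 of wt+/mt- had the high actin ratios, and the counts depended on them: 117 genes and 8 lists were called without both, 287 genes and 5 lists with the actin ratio as a covariate, 701 without replicate 1 and 665 without replicate 2. Without wt-/mt- replicate 2, 2533 were called. With 1 weight per genotype 399 were called, all 399 among the 1670, with 0 of the G2/M, 0 of the S phase and 0 of the MYC genes, 6 canonical and 4 lymphocyte targets. Probe sets of Cotl1 (0.97 to 2.88), Cdyl2 (-5.11 to -1.16), Ehf (-4.65 to -2.08), Bach2 (-3.94 to -0.63) and Trp53inp1 (-2.23 to -0.23) differed in size.

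The other 6 called lists of this comparison were oxidative phosphorylation, higher (4 of 24 rose, 4 adjusted over the list alone, camera adjusted p = 0.0125), somatic hypermutation, class switching and DNA repair, higher (5 rose, and 6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0391) and B cell identity, lower (3 fell, 5 adjusted over the list alone, adjusted p = 0.0263). Also lower were mTORC1 with lysosome and autophagy (3 fell, 2 adjusted over the list alone, adjusted p = 0.0263), p53 targets (4 fell, 5 adjusted over the list alone, adjusted p = 0.0374) and trafficking and adhesion (6 fell and 1 rose, likewise adjusted over the list alone, adjusted p = 0.0421). All had an adjusted p = 0.393 with an estimated correlation, except mTORC1 with 0.610. The calls of oxidative phosphorylation and of hypermutation and repair ended after quantile normalization. Under 1 weight per genotype 1 gene rose in each of those lists, and 2 B cell identity genes, 0 mTORC1 genes, 1 p53 target and 4 trafficking genes fell. Ndufa4 rose by 1.12 (SE 0.20), H2ax by 1.04 (SE 0.20) and Brca1 by 1.19 (SE 0.32), whose probe sets ranged from 0.51 to 1.19. Cd22, an inhibitory receptor, fell by 1.05 (SE 0.23), S1pr1, a receptor for sphingosine 1-phosphate, by 1.76 (SE 0.24) and the integrin chain Itgb2 by 0.95 (SE 0.13).

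Loss of the mutant allele in cells without the wild-type allele (wt-/mt- against wt-/mt+) raised Anxa10 by 5.54 (SE 0.60, n = 3 arrays per genotype, limma adjusted p = 0.000223), Havcr1 by 4.47 (SE 0.35), Clec2i by 3.85 (SE 0.28), Mpeg1 by 3.80 (SE 0.64), Klhl6 by 3.78 (SE 0.46), Lgals1 by 3.73 (SE 0.91), Cybb by 3.44 (SE 0.37) and Pla2g7 by 3.13 (SE 0.50). Falls were found for Dnaic2 (-5.95, SE 0.74), Ehf (-5.38, SE 0.34), Zfyve28 (-5.14, SE 0.51) and Bach2 (-4.52, SE 0.45). Wfdc21 (-4.39, SE 0.60), Lct (-4.31, SE 0.33), Mndal (-3.64, SE 0.44) and Lnx1 (-3.56, SE 0.29) fell too. Of 31 canonical FOXO targets 15 fell and 1 rose, with 21 and 1 adjusted over the list alone (median -0.59, camera adjusted p = 1.12e-06, adjusted p = 0.593 with an estimated correlation). The gene that rose was Cdkn1b, which encodes the CDK inhibitor p27 (1.42, SE 0.44), although its other probe set gave 0.27 and the call ended under 1 weight per genotype. Of 14 lymphocyte targets 7 fell, 9 adjusted over the list alone (median -0.68, adjusted p = 0.000356, adjusted p = 0.593 with an estimated correlation). MYC and ribosome biogenesis had 13 rises of 33, with 21 higher and 1 lower adjusted over the list alone (median 0.49, adjusted p = 1.12e-06, adjusted p = 0.717 with an estimated correlation), with Srm at 1.03, Nop2 at 0.95 and Mybbp1a at 0.91. In the G2/M list 2 of 27 rose, 0 adjusted over the list alone (median 0.32, adjusted p = 0.0281, adjusted p = 0.773 with an estimated correlation). Lmo2 rose by 2.38 (SE 0.32), Hk1, a hexokinase, by 1.85 (SE 0.19) and Mef2b by 2.01 (SE 0.30), while Bmf (-2.84, SE 0.31) and H2-Ob (-2.89, SE 0.29) fell. In all 2386 genes were called, 1117 higher and 1269 lower, with 4064 at an unadjusted p under 0.05 and 2323 called genes without overlap. With median-centred arrays 2330 were called, 855 higher and 1475 lower, and with 1 weight per genotype 923, 319 higher and 604 lower, 915 of them among the 2386. That fit called 10 canonical and 5 lymphocyte targets, 6 MYC and ribosome biogenesis genes and 0 G2/M genes. In it the call of the G2/M list ended and B cell identity was called. Probe sets ranged from -4.52 to -1.11 for Bach2, from -2.84 to -0.49 for Bmf and from 1.68 to 3.44 for Cybb. Without 1 of the wt-/mt+ arrays in turn, 1443, 1121 and 1424 genes were called. This comparison crosses the difference in spiked controls between mt- and mt+ arrays (bioD -0.83, lys 1.22), so it cannot tell the allele from that difference. The wt-/mt- arrays also had the widest spread (median SD 0.261) and shifts of whole chromosomes.

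Loss of the mutant allele in cells with the wild-type allele (wt+/mt- against wt+/mt+) raised Grk3, a kinase of G protein-coupled receptors, by 2.02 (SE 0.26, n = 3 arrays per genotype, limma adjusted p = 0.0393) and Mctp1 by 1.91 (SE 0.26, adjusted p = 0.0393). Ckm rose by 0.89 (SE 0.14), Smox, spermine oxidase, by 0.79 (SE 0.12) and Cyp2b10 by 0.72 (SE 0.11). Vpreb3, of the B cell identity list, fell by 1.43 (SE 0.21), Stap2 by 1.46 (SE 0.20), Neo1 by 1.41 (SE 0.22), Snhg16 by 1.37 (SE 0.18), Pik3r6, a regulatory subunit of PI3K, by 0.97 (SE 0.14), Ugcg by 0.91 (SE 0.13), Sh3bp1 by 0.87 (SE 0.14) and Surf4 by 0.68 (SE 0.11). Probe sets of Ckm (0.11 to 0.89), Stap2 (-1.46 to 0.03), Neo1 (-1.41 to 0.36), Snhg16 (-1.37 to 0.08), Surf4 (-0.68 to 0.00) and Ugcg (-0.91 to -0.23) disagreed. In all 21 genes were called, 13 higher and 8 lower, with 1704 at an unadjusted p under 0.05 and all 21 without overlap. With median-centred arrays 10 were called, 4 higher and 6 lower, with a second quantile normalization 9, 4 of them higher, and with values centred per chromosome 14, 5 higher and 9 lower. The 21 were among 950 genes called with 1 weight per genotype, 679 higher and 271 lower, and 0 genes were called with the actin ratio as a covariate. Without 1 array in turn the count was 0 for each of wt+/mt+ replicates 1, 2 and 3, wt-/mt+ replicates 1, 2 and 3 and wt+/mt- replicate 1, 1 without wt+/mt- replicate 2, and 111, 101 and 150 without each wt-/mt- array, which serve here only to estimate the spread.

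After loss of the mutant allele, 6 lists were called, all lower, with 0 members called in each. The dark zone list had a median of -0.24 (16 genes, 1 lower adjusted over the list alone, camera adjusted p = 0.00587). Canonical FOXO targets had a median of -0.11 (31 genes, 0 adjusted over the list alone), germinal center identity one of -0.20 (16 genes, 1 lower adjusted over the list alone) and S phase one of -0.21 (24 genes, 0 adjusted over the list alone), each with an adjusted p = 0.0282. Antigen presentation (median -0.21) and oxidative phosphorylation (median -0.08) had 0 members adjusted over the list alone and an adjusted p = 0.0410. With an estimated correlation the adjusted p was 0.925 for S phase and 0.711 for the other 5. In wt+/mt- replicates 1, 2 and 3 the median relative to the wt+/mt+ mean was -0.41, -0.44 and 0.10 for the dark zone list and -0.38, -0.34 and 0.21 for S phase, so both lay below 0 only in the replicates with high actin ratios, while the other 4 medians were below 0 in all 3 replicates. The calls of canonical FOXO targets, germinal center identity, S phase and antigen presentation ended after quantile normalization, with median-centred arrays and after centring per chromosome, and that of oxidative phosphorylation after quantile normalization. Without wt+/mt- replicate 2 the count was 0, and without replicates 1 and 2 it was 2. Under 1 weight per genotype 3 canonical targets and 1 gene each of the dark zone, germinal center identity and antigen presentation lists fell.

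Loss of the wild-type allele in cells with the mutant allele (wt-/mt+ against wt+/mt+) gave all 27 G2/M genes a change above 0, with a median of 0.55 (n = 3 arrays per genotype, camera adjusted p = 4.23e-16, adjusted p = 0.506 with an estimated correlation), and 23 of 24 S phase genes, with a median of 0.39 (adjusted p = 3.42e-06, adjusted p = 0.506 with an estimated correlation). No single member was called, 0 adjusted over the list alone. Birc5 changed by 0.64, Ccnb2 by 0.64, Cdk1 by 0.58 and Plk1 by 0.49, each with an adjusted p of 1.00. Hypermutation, class switching and DNA repair genes had a median of 0.17 (20 of 24 above 0, adjusted p = 0.0116, adjusted p = 0.506 with an estimated correlation) and cholesterol synthesis genes one of 0.16 (adjusted p = 0.0239, adjusted p = 0.666 with an estimated correlation). Lower lists were MYC and ribosome biogenesis (median -0.04, adjusted p = 0.00108), lymphocyte targets (median -0.15, adjusted p = 0.00294), B cell identity (median -0.12, adjusted p = 0.00392), B cell receptor and PI3K signalling (median -0.09, adjusted p = 0.00392), antigen presentation (median -0.14, adjusted p = 0.00592) and immediate early and heat shock genes (median -0.14, adjusted p = 0.0474), each with an adjusted p = 0.506 with an estimated correlation. Canonical FOXO targets (median -0.04) and mTORC1 with lysosome and autophagy (median -0.05) were lower with an adjusted p = 0.0179, and adjusted p = 0.539 with an estimated correlation. Adjusted over the list alone, 1 B cell identity gene was lower and 0 genes of the other 11 called lists passed. The call of immediate early and heat shock genes ended after quantile normalization, with median-centred arrays and after centring per chromosome, and that of antigen presentation after centring per chromosome. Over all genes limma called 0, with 412 at an unadjusted p under 0.05, and fry called 0 lists. With 1 weight per genotype limma called 19 genes, 12 higher and 7 lower, among the list members 1 B cell identity gene, lower, and with the fit limited to the 2 genotypes 53.

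The mutant allele alone was set against the wild-type allele alone (wt-/mt+ against wt+/mt-). These genotypes lie on either side of the hybridisation difference (bioD -0.83, mt- minus mt+), which cannot be told apart from the alleles here. Mgmt, a DNA repair methyltransferase, was higher with the mutant allele by 1.38 (SE 0.16, n = 3 arrays per genotype, limma adjusted p = 0.0393), Tmem243 by 1.27 (SE 0.19), Pik3r6 by 0.95 (SE 0.14) and Cdc14a by 0.63 (SE 0.08), although the other probe set of Cdc14a gave -0.04. Lower with the mutant allele were Grk3 (-2.02, SE 0.26), Mctp1 (-1.86, SE 0.26), 4930447F24Rik (-0.82), Slc7a4 (-0.75), Cyp2b10 (-0.72) and Atp8b3 (-0.66). These 10 genes were all that was called, with 1881 at an unadjusted p under 0.05 and 10 without overlap, and median-centred arrays gave 3, 2 of them higher. The G2/M list had a median of 0.58 (26 of 27 above 0, camera adjusted p = 1.06e-09, adjusted p = 0.782 with an estimated correlation), S phase one of 0.58 (23 of 24, adjusted p = 1.18e-07, adjusted p = 0.782 with an estimated correlation), the dark zone list one of 0.45 (16 of 16, adjusted p = 1.82e-05, adjusted p = 0.579 with an estimated correlation) and the hypermutation and repair list one of 0.22 (21 of 24, adjusted p = 0.00355, adjusted p = 0.579 with an estimated correlation). In these 4 lists 0 members were called, also 0 adjusted over the list alone, and 1, 3, 1 and 1 were called under 1 weight per genotype. The G2/M, S phase and dark zone medians lay below the wt+/mt+ mean in wt+/mt- replicates 1 and 2 and above it in replicate 3. Without wt+/mt- replicates 1 and 2 together 0 lists and 2 genes were called, and with the actin ratio as a covariate 0 genes. With 1 weight per genotype 835 genes were called, 337 higher and 498 lower. Single arrays moved the count too: it was 3, 0 and 0 without wt+/mt+ replicates 1, 2 and 3, 1, 0 and 2 without those of wt-/mt+, 0, 4 and 118 without those of wt+/mt-, and 112, 113 and 232 without those of wt-/mt-.

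The interaction asks whether losing both alleles differs from the sum of the single losses. Clec2i exceeded the sum by 4.79 (SE 0.39, n = 3 arrays per genotype, limma adjusted p = 0.000550), Sash3 by 4.45 (SE 0.90), Anxa10 by 4.05 (SE 0.84), Pla2g7 by 3.89 (SE 0.71) and Havcr1 by 3.58 (SE 0.49). Sash3 was at 9.53 in wt+/mt+ and 9.74 in wt-/mt-, and at 7.02 and 7.80 in the single losses. Zfyve28 (-4.89, SE 0.72), Ehf (-4.73, SE 0.48), Dnaic2 (-4.55, SE 1.04), Lct (-4.18, SE 0.47), Cdyl2 (-3.95, SE 0.93) and Bach2 (-3.93, SE 0.64) lay below the sum. So did Pik3ip1 (-2.81, SE 0.31), Cxcr4 (-2.86, SE 0.59), Bmf (-2.41, SE 0.44) and H2-Ob (-2.32, SE 0.41). Probe sets ranged from -3.95 to -1.39 for Cdyl2, from -3.93 to -0.90 for Bach2 and from -2.41 to -0.26 for Bmf, which gave -0.31 and no call without probe sets for several transcripts. In all 360 genes were called, 96 positive and 264 negative, with 2104 at an unadjusted p under 0.05, and with 1 weight per genotype also 360, of which 268 were the same genes. Positive lists were MYC and ribosome biogenesis (median 0.50, 1 gene of 33, 7 adjusted over the list alone, camera adjusted p = 1.54e-10, adjusted p = 0.555 with an estimated correlation), S phase (0.50, 1 of 24, 1 adjusted over the list alone, adjusted p = 0.00131, adjusted p = 0.887 with an estimated correlation), G2/M (0.28, 0 of 27, 0 adjusted over the list alone, adjusted p = 0.00138, adjusted p = 0.887 with an estimated correlation) and oxidative phosphorylation (0.15, 0 of 24, 1 adjusted over the list alone, adjusted p = 0.0168, adjusted p = 0.718 with an estimated correlation). Negative lists were canonical FOXO targets (-0.58, 5 of 31, 9 adjusted over the list alone, adjusted p = 0.000460, adjusted p = 0.697 with an estimated correlation), lymphocyte targets (-0.44, 3 of 14, 4 adjusted over the list alone, adjusted p = 0.00401, adjusted p = 0.555 with an estimated correlation) and interferon response (-0.25, 0 of 18, 3 adjusted over the list alone, adjusted p = 0.0378, adjusted p = 0.555 with an estimated correlation). The oxidative phosphorylation call ended after quantile normalization, and that of interferon response after quantile normalization and after centring per chromosome. The fit with 1 weight per genotype called 1 MYC and 1 oxidative phosphorylation gene, 0 S phase and 0 G2/M genes, 3 canonical and 3 lymphocyte targets and 1 interferon response gene. Without wt+/mt- replicates 1 and 2, 56 genes and 3 lists were called, and with the actin ratio as a covariate 166 and 3. Single arrays moved the count: without wt+/mt+ replicates 1, 2 and 3 it was 123, 144 and 118, without those of wt-/mt+ 128, 144 and 171, without wt+/mt- replicates 1 and 2 197 and 138, and without those of wt-/mt- 926, 988 and 767.

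Across 11458 genes, the changes after wild-type loss with and without the mutant allele had a Pearson correlation of 0.0779 and a Spearman correlation of 0.0668, with 0 genes called in both (limma called 0 and 1670). With 1 array left out the Pearson value ranged from 0.0115 (without wt-/mt+ replicate 3) to 0.165 (without wt+/mt+ replicate 1) and the Spearman value from -0.00298 to 0.161 (without the same arrays). Without wt+/mt- replicates 1 and 2 both turned, to -0.0495 and -0.0319. The changes after mutant loss with and without the wild-type allele had a Pearson correlation of 0.359 and a Spearman correlation of 0.343. Unlike the wild-type losses, both of these mutant losses set mt- against mt+ arrays. They share the hybridisation difference (bioD -0.83), which alone could give a positive correlation and calls in the same direction. Of 15 genes called in both, 14 went the same way, and 1, Vpreb3, singled out after its values were seen, did not: it fell by 1.43 with the wild-type allele and had a change of 0.81 without it. After wild-type loss with the mutant allele Vpreb3 had a change of -1.67 (limma adjusted p = 0.0830), not called. That count of 15 was 0 without any 1 of wt+/mt+ replicates 1, 2 and 3, wt-/mt+ replicates 1, 2 and 3 and wt+/mt- replicate 1, 1 without wt+/mt- replicate 2, 10 without its replicate 3, and 78, 67 and 91 without wt-/mt- replicates 1, 2 and 3. Without wt+/mt- replicates 1 and 2 together it was 1. Wild-type loss and mutant loss from wt+/mt+ share the wt+/mt+ arrays, and had a Pearson correlation of 0.137 against 0.343 in simulated unchanged groups (0.287 to 0.388 over 100 draws). Their covariance was 0.00659 against a simulated 0.00633 (0.0054 to 0.00729). Noise in these draws was independent between genes, unlike that of real arrays. The simulated ranges leave out noise shared by genes, so they cannot show whether either value departs from chance. Both values depended on the wt+/mt- arrays: the correlation was 0.224 without replicate 1, 0.0151 without replicate 3 and 0.353 without replicates 1 and 2, and the covariance 0.0106, 0.000836 and 0.0181, with no unchanged groups simulated for these fits. Without wt+/mt+ replicates 2 and 3 in turn the correlation was 0.206 and 0.215 and the covariance 0.0106 and 0.0111, and without wt-/mt+ replicate 1 the correlation was 0.088. Of the genes called after loss of both alleles, 1230 were also called after wild-type loss without the mutant allele, 510 higher and 720 lower in both and 0 in opposite directions, where independent lists would share 88.7 and 93.6. Both comparisons hold the wt-/mt- arrays, and of 100 simulated sets with no difference between wt-/mt- and wt+/mt- and with the correlated noise of the real arrays, 10 shared as many (highest 3611). When both comparisons had 1 weight per genotype, 342 were shared, and 8 of the 100 sets had as many (highest 2006). Neither share of sets is under 0.05, so chance cannot be excluded for either overlap. Of these 342, 199 were also called in the same direction after wild-type loss without the mutant allele with the actin ratio as a covariate. Fewer still were called without wt+/mt- replicates 1 and 2, a fit that leaves 1 array in that genotype.

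**Figure D4:**
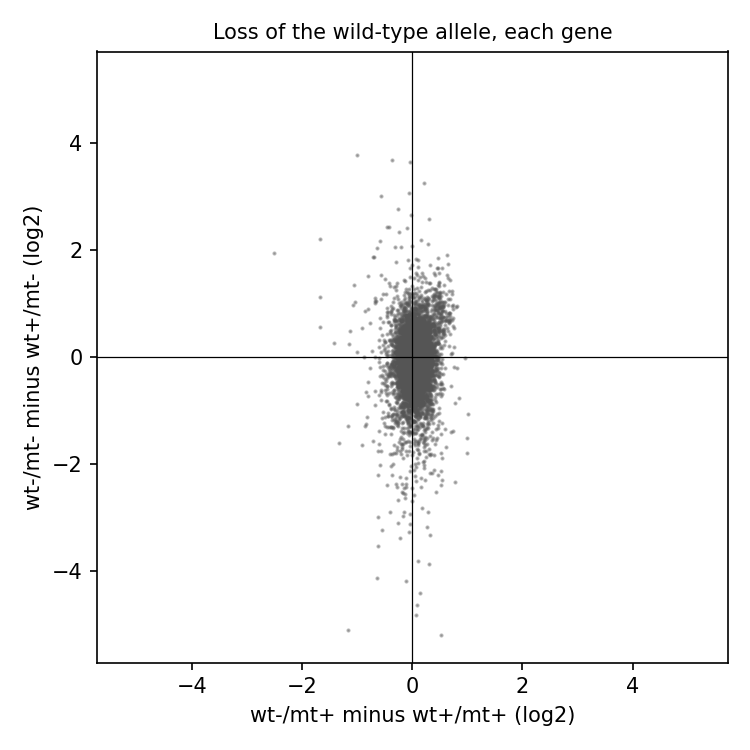
Log2 change of each gene after loss of the wild-type allele with the mutant allele (horizontal, wt-/mt+ minus wt+/mt+) and without it (vertical, wt-/mt- minus wt+/mt-), with 1 point for each of 11458 genes. The Pearson correlation was 0.0779.

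**Figure D5:**
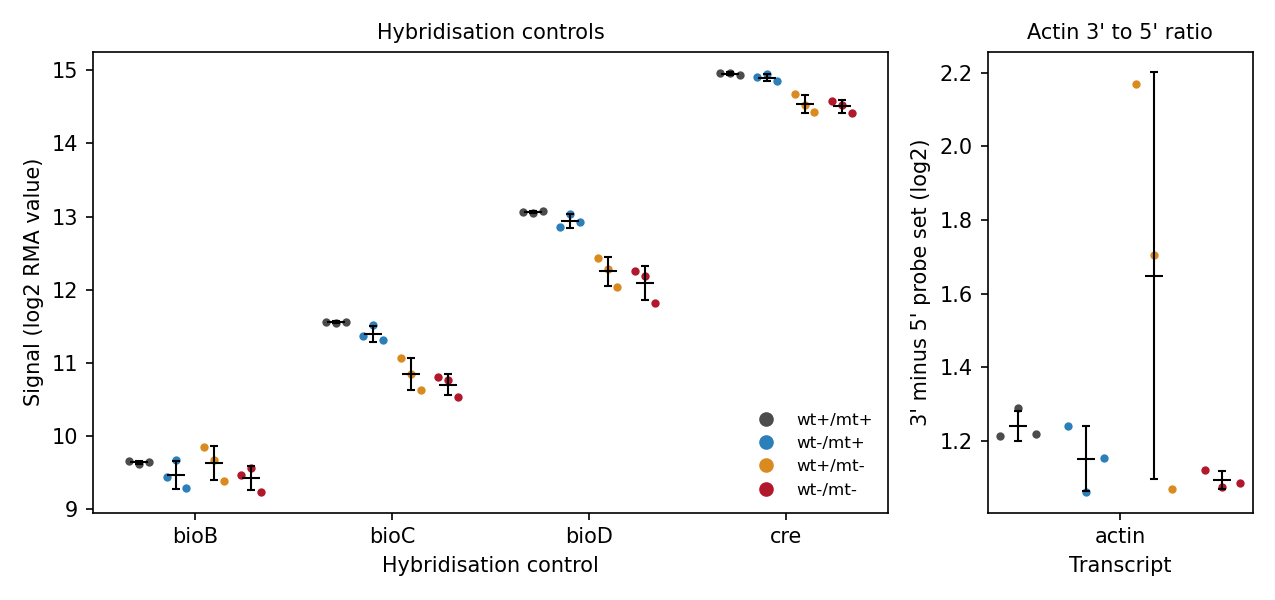
Signal (log2) of 4 spiked hybridisation transcripts and the log2 actin 3' to 5' ratio on each array, coloured by genotype, with points for arrays and bars for the mean ± SD of 3 arrays. bioD lay between 12.9 and 13.1 on the mt+ arrays and between 11.8 and 12.4 on the mt- arrays.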

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

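The tests of the hybridisation difference, of myeloid RNA and of RNA quality were chosen only after the results they measure were seen, as were 1 weight per genotype, the actin covariate and the fits without chosen arrays. The test of chromosome copies by centring per chromosome was also added after seeing the data, with its bounds written before its own result. The other splits of the arrays were set beforehand.

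The effects of losing an allele differed with the other allele for 360 genes by the interaction test of limma. Lists called by camera at the preset correlation were canonical FOXO targets (-0.58), Foxo1 targets of lymphocytes (-0.44), interferon response (-0.25), G2/M (0.28), MYC and ribosome biogenesis (0.50), oxidative phosphorylation (0.15) and S phase (0.50). With an estimated correlation their adjusted p lay between 0.555 and 0.887, and 48 of 100 splits of the arrays called as many lists, so a difference is not established for them. Foxo1 itself was at -1.71. Genes above the sum of single losses were Clec2i (4.79), Sash3 (4.45), Anxa10 (4.05), Pla2g7 (3.89), Havcr1 (3.58), Ncf4 (3.13), Cybb (3.05), Tnni2 (2.90), Klhl6 (2.86), Rassf4 (2.77), Vpreb3 (2.24), Lmo2 (2.07), Mef2b (2.05), Hk1 (1.96), Bid (1.23), Mybbp1a (0.88) and Ung (0.84). Genes below it were Zfyve28 (-4.89), Ehf (-4.73), Dnaic2 (-4.55), Lct (-4.18), Cdyl2 (-3.95), Bach2 (-3.93), Lnx1 (-3.64), Gm8369 (-3.51), Ppp3cc (-3.46) and B3gnt5 (-3.23). Further list members below it were Cxcr4 (-2.86), Pik3ip1 (-2.81), Bmf (-2.41), H2-Ob (-2.32), Trp53inp1 (-2.28), Traf1 (-1.75), Irs2 (-1.66), Rgs2 (-1.64), Lmo4 (-1.20), Itgb2 (-1.02), Cd72 (-0.995) and Bnip3 (-0.77).

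Of the spiked control transcripts, 5 differed between the 6 mt- and the 6 mt+ arrays: bioC by -0.71, bioD by -0.83, cre by -0.40, lys by 1.22 and phe by 0.80 (log2). Differences of -0.026 for bioB and 0.74 for dap did not pass the test. The highest actin 3' to 5' ratio was 2.17, in a wt+/mt- array.

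Of 100 splits of the 12 arrays into 4 groups of 3, the real one included, 1 called as many genes by the F test (2202, highest other 831) and 1 by the interaction (360, highest other 179). An arbitrary grouping of these arrays thus rarely gave such an F test count. The other splits mostly break up the wt-/mt- arrays, which stand apart from the rest. Their differences then widen the spread within groups, so the splits cannot show whether the interaction count exceeds chance. Nor do the splits tell a clone from a genotype. For the interaction lists 48 of 100 splits called as many (7, highest other 14), so chance cannot be excluded there. The 10 splits of each pair of genotypes are too few for a share under 0.05. Of those 10, 1 called as many genes after loss of both alleles (2535, highest other 0), 1 after mutant loss (21, highest other 0), 10 after wild-type loss (0, highest other 0), 1 for the mutant against the wild-type allele alone (10, highest other 0), 1 after mutant loss without the wild-type allele (2386, highest other 1) and 1 after wild-type loss without the mutant allele (1670, highest other 4). For lists in the same order, 5 splits called as many (9, highest other 12), 2 (6, highest other 7), 1 (12, highest other 6), 6 (4, highest other 6), 7 (4, highest other 11) and 4 (11, highest other 14).

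The changes after loss of both alleles were set against the hybridisation difference and against chromosome copies. Loss of the mutant allele alone crosses the same hybridisation difference, yet it moved the 2535 genes by a median of 0.179 in the called direction (0.165, 0.173 and 0.224 in wt+/mt- replicates 1, 2 and 3) against 0.641 after loss of both alleles. That ratio of 0.279 lies below those of 100 simulated sets with no difference between wt-/mt- and wt+/mt- (0.53 to 1.07). Those sets took the observed wt-/mt- means as true, noise included, which pushes their ratios up. The 2535 genes were also chosen on the wt-/mt- arrays, which raises 0.641 more than 0.179. The low ratio therefore cannot show whether the hybridisation difference is the whole cause, and it stays open. After centring per chromosome 84.6% of the calls remained in the same direction, which argues against direct shifts of whole chromosomes as the whole cause. Centring does not remove gains or losses of parts of chromosomes, nor effects on genes of other chromosomes. Extra or lost copies therefore stay open as a cause. A biological effect of losing both alleles stays open as a hypothesis, and so does a difference between clones, which the labels do not separate from genotype.

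Cybb, Ncf4, Mpeg1 and Cd68, grouped here after their values were seen, are known from phagocytes and rose after loss of both alleles. The myeloid marker list itself was not called, with 1 of 5 genes higher, 2 adjusted over the list alone (camera adjusted p = 0.597, adjusted p = 0.699 with an estimated correlation), and its members Tyrobp (2.00, SD 1.98 in wt-/mt-, limma adjusted p = 0.0627), Csf1r (0.05), Adgre1 (-0.38) and Fcer1g (-0.07) did not pass the test over all genes. RNA of myeloid cells would bring abundant transcripts with it, but 8 of these (Lyz2, S100a8, S100a9, C1qa, C1qb, Apoe, Cd14 and Itgam) had a median change of 0.074 (-0.01 to 0.53) and levels between 4.26 and 5.76 in wt-/mt-, where the array medians lay between 6.19 and 6.25, which argues against it. Expression of these genes by the lymphoma cells themselves stays open and was not tested.

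The calls after loss of the mutant allele alone were set against RNA quality, since wt+/mt- replicates 1 and 2 had high actin ratios. Of 15 genes called without replicate 3, all 15 went the same way in replicate 3, where the median change in the called direction was 0.489 against 0.987 in replicates 1 and 2, a ratio of 0.496. Replicate 3 was read against the same wt+/mt+ mean that served to call these genes, so error in that mean favours agreement. The ratio lies between the bounds set for and against this explanation, so lower RNA quality may be part of it and cannot be told apart from the genotype. The hybridisation difference (bioD -0.83) coincides with the mutant allele, so no comparison separates them. A biological effect of the allele stays open too.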

How the results depend on the processing

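Added after seeing the data were 1 weight per genotype, the actin covariate, wt+/mt- replicates 1 and 2 left out together, centring per chromosome and the wt-/mt- arrays left out of the fit. No paired analysis was possible because the array numbers run on from genotype to genotype, so no 2 genotypes share a number. The signal of the arrays limits what can be read of dim genes, as for the dim Foxo1 probe set. Except where a reason is given, the cause was not tested.

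Under 1 weight per genotype, limma called 866 genes after loss of both alleles, 950 after mutant loss, 19 after wild-type loss, 835 for the mutant against the wild-type allele alone, 923 after mutant loss without the wild-type allele and 399 after wild-type loss without the mutant allele, and the unequal spread is what this fit models. With arrayWeights the counts in that order were 1250, 4423, 136, 3941, 1085 and 880, with 5371 for the F test and 605 for the interaction. That fit gave wt+/mt- replicate 2, with a high actin ratio, a weight of 7.34 against 0.63 and 0.59 for replicates 1 and 3. In wt+/mt+, replicate 2 had 6.13 against 0.86 and 2.45 for replicates 1 and 3. Counts that involve these genotypes thus lean on single arrays. With only the 2 genotypes in the fit they were 813, 574, 53, 393, 519 and 115. Without the wt-/mt- arrays, mutant loss had 962, wild-type loss 6 and the comparison of single alleles 1191. With a change of at least 1 as well, the F test had 651, loss of both alleles 541, mutant loss 6, the single alleles 4, mutant loss without the wild-type allele 562, wild-type loss without the mutant allele 431 and the interaction 221, by the stricter rule itself.

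Mutant loss had 100 calls without a filter, 42 with a filter at the 25th percentile, 0 with the mean of a gene's probe sets, 9 after quantile normalization, 10 with median-centred arrays, 33 with trend and robust eBayes and 53 with every probe set tested. Of 1704 genes at an unadjusted p under 0.05 in limma, 21 were called in the reported fit. Genes called after mutant loss in both backgrounds numbered 58, 29, 0, 5 and 6 in the first 5 of these settings and 8 after centring per chromosome. The Spearman correlation of the mutant losses was 0.403 without a filter and 0.394 at the 25th percentile, and the Pearson correlation of wild-type with mutant loss was 0.219 without a filter. The single alleles had 1 call with the mean of probe sets, 25 without probe sets for several transcripts and 3 with median-centred arrays, where wild-type loss had 1.

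Called lists numbered 0 in each of the 7 comparisons with an estimated correlation. With fry, mutant loss had 1 and the single alleles 1, in both the T cell markers, which camera did not call, so none of the 6 and 4 lists called by camera held, nor any of the 12 after wild-type loss, where fry had 0. Mutant loss without the wild-type allele had 9, among them 3 of the 4 called by camera, not G2/M. Camera calls that fry did not make were also S phase, antigen presentation and mTORC1 after loss of both alleles, mTORC1 and hypermutation and repair after wild-type loss without the mutant allele, and G2/M, S phase and oxidative phosphorylation for the interaction. T cell markers, not called by camera, were called by fry after loss of both alleles and after mutant loss without the wild-type allele too. Forkhead family members and trafficking were further fry calls after loss of both alleles, and further ones after mutant loss without the wild-type allele were B cell identity, p53 targets, interferon response, forkhead family and trafficking. After wild-type loss without the mutant allele they were forkhead family and interferon response, and for the interaction forkhead family and trafficking. Camera with 1 weight per genotype also called B cell identity and lymphocyte targets after mutant loss and p53 targets for the interaction. Mutant loss had 3 lists without probe sets for several transcripts, 1 after quantile normalization, 2 with median-centred arrays and 2 after centring per chromosome.

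With the actin covariate, mutant loss had 0 calls, the single alleles 0, wild-type loss without the mutant allele 287 and 5 lists, and the interaction 166 and 3 lists, with Foxo1 at -1.46. Without wt+/mt- replicates 1 and 2, where 1 array is assumed to vary like the other groups, the F test had 1047, mutant loss 2 and 2 lists, the single alleles 2 and 0 lists, wild-type loss without the mutant allele 117, and the interaction 56 and 3 lists. Foxo1 was then at -0.0445 after mutant loss, -1.60 after wild-type loss without the mutant allele and -1.43 for the interaction. The correlations of the wild-type losses turned to -0.0495 (Pearson) and -0.0319 (Spearman), 1 gene was called after mutant loss in both backgrounds, and wild-type and mutant loss had a Pearson correlation of 0.353 and a covariance of 0.0181.

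The dim Foxo1 probe set gave 0.26 after loss of both alleles, 0.20 after wild-type loss, 0.0625 after mutant loss without the wild-type allele, -0.0683 after wild-type loss without the mutant allele and -0.27 for the interaction, and another probe set gave -1.65 for the interaction, not called. Igll1 turned to -0.25 with the mean of probe sets after loss of both alleles. Without probe sets for several transcripts it was at -0.95, Pfkl at -0.13 and Ighm at 0.51, with Pfkl at -0.29 and Ighm at 0.25 after mutant loss without the wild-type allele, Ighm at 0.29 after wild-type loss without the mutant allele and Neo1 at 0.36 after mutant loss, each from another probe set. With 1 array left out Neo1 ranged from -1.61 (without wt+/mt+ replicate 3) to 0.34 (without wt-/mt+ replicate 2), with 0.23 without wt+/mt+ replicate 1.

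With 1 array left out in turn, the F test had 1296 (without wt+/mt+ replicate 2) to 2797 calls, loss of both alleles 1251 (without wt+/mt+ replicate 2) to 3120, mutant loss 0 to 150 (without wt-/mt- replicate 3), wild-type loss 0 to 1 (1 without each wt-/mt- array), the single alleles 0 to 232 (without wt-/mt- replicate 3), mutant loss without the wild-type allele 1121 (without wt-/mt+ replicate 2) to 2975, wild-type loss without the mutant allele 665 (without wt+/mt- replicate 2) to 2533 (without wt-/mt- replicate 2), and the interaction 118 (without wt+/mt+ replicate 3) to 988 (without wt-/mt- replicate 2). Lists ranged from 0 (without wt+/mt- replicate 2) to 9 (without wt-/mt- replicate 2) after mutant loss, with 3 without each of wt+/mt+ replicates 2 and 3 and wt+/mt- replicate 3, from 3 to 7 (without wt-/mt- replicate 1) after mutant loss without the wild-type allele and from 7 (without wt-/mt- replicate 2) to 11 after wild-type loss without the mutant allele. The Foxo1 interaction ranged from -1.88 to -1.41 and was not called without wt+/mt+ replicates 1, 2 or 3, wt-/mt+ replicates 1 or 3 or wt+/mt- replicates 1 or 2. Correlations ranged from 0.287 to 0.4004 (Pearson) and 0.263 to 0.398 (Spearman) for mutant loss, from 0.0115 to 0.165 and -0.00298 (without wt-/mt+ replicate 3) to 0.161 for wild-type loss, and from 0.0151 (without wt+/mt- replicate 3) to 0.224 between the alleles, with a covariance of 0.000836 to 0.0111. Genes called in both backgrounds ranged from 0 to 91 (without wt-/mt- replicate 3) for the mutant allele and 0 to 1 for the wild-type allele. Of 4329 results for named genes with 1 array left out, 3384 kept direction and call, 943 lost the call and 2 turned, and under the other settings 3703, 885 and 8 of 4596. These totals mix unlike settings. With only the 2 genotypes in the fit 193 of 324 lost the call, and with 1 weight per genotype 139 of 363. At the 25th percentile filter 12 of 363 lost it, and with trend and robust eBayes 0 of 363.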

Other observations

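The test of whole-chromosome shifts and the centring per chromosome were chosen only after the data were seen.

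Loss of both alleles moved single members of the lists that were not called. Mef2b, a transcription factor of germinal center B cells, rose by 2.16 while Gcsam fell by 2.00, Lmo4 by 1.41 and Lmo2 rose by 1.35 (log2, n = 3 arrays per genotype, limma). Germinal center identity had 2 rises and 3 falls of 16 (2 and 6 adjusted over the list alone, camera adjusted p = 0.0733), the dark zone list 5 and 5 of 16 (5 and 5 adjusted over the list alone, adjusted p = 0.561) and the light zone list 3 and 2 of 18 (4 and 2 adjusted over the list alone, adjusted p = 0.933). Slamf7 fell by 2.40 and Xbp1, a factor of secretory cells, by 1.33 in the plasma cell list, with 3 rises and 3 falls of 19 (3 and 5 adjusted over the list alone, adjusted p = 0.432). Syk, a kinase downstream of the B cell receptor, fell by 1.52 in the receptor and PI3K list, with 1 rise and 8 falls of 27 (2 and 8 adjusted over the list alone, adjusted p = 0.0594). In trafficking and adhesion Rgs2 fell by 1.72 and S1pr1 by 1.49, with 1 rise and 4 falls of 19 (2 and 5 adjusted over the list alone, adjusted p = 0.0727). Foxp1 fell by 1.32 and Foxm1, a factor of mitotic genes, rose by 0.89 among forkhead family members, with 1 rise and 2 falls of 7 (1 and 2 adjusted over the list alone, adjusted p = 0.0865). Traf1 fell by 1.41 and Cflar, an inhibitor of caspase-8, by 1.41, and the NF-kB list had 2 falls of 14 (2 adjusted over the list alone, adjusted p = 0.747). Cflar had probe sets from -1.41 to -0.42. Under 1 weight per genotype, chosen after seeing the data, rises and falls numbered 1 and 2 for germinal center identity, 0 and 4 for the dark zone, 0 and 1 for the light zone, 1 and 2 for plasma cells, 0 and 5 for the receptor and PI3K list, 1 and 3 for trafficking, 1 and 2 for the forkhead family and 0 and 2 for NF-kB targets, and camera called the germinal center identity and receptor lists.

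Hk1 rose by 1.36 in the glycolysis list, with 4 rises and 1 fall of 17 (likewise adjusted over the list alone, camera adjusted p = 0.338), and Ndufa4 by 0.95 in oxidative phosphorylation, with 1 rise of 24 (1 adjusted over the list alone, adjusted p = 0.389). Shmt2, a mitochondrial enzyme of serine metabolism, rose by 1.20 (0.37 to 1.29 over probe sets), with 3 rises of 23 amino acid stress genes (2 adjusted over the list alone, adjusted p = 0.561). Nsdhl fell by 0.89 in cholesterol synthesis, with 2 rises and 2 falls of 23 (2 and 1 adjusted over the list alone, adjusted p = 0.933). Ccnd1, a G1 cyclin, rose by 1.35, with 2 rises and 1 fall of 17 in the CDK inhibitor and G1 list (likewise adjusted over the list alone, adjusted p = 0.561). H2ax rose by 1.55, with 4 rises of 24 hypermutation, class switching and repair genes (4 adjusted over the list alone, adjusted p = 0.409). Gbp2 fell by 0.97 and Ifit1 by 0.78, with 2 rises and 4 falls of 18 interferon response genes (likewise adjusted over the list alone, adjusted p = 0.353). Jund fell by 0.80, a call that ended with the mean of its probe sets (-0.12) and with 1 weight per genotype, with 1 rise and 2 falls of 17 immediate early and heat shock genes (0 adjusted over the list alone, adjusted p = 0.286). Among markers of other cells, Cd68 rose by 1.93 with 1 rise of 5 myeloid genes (2 adjusted over the list alone, adjusted p = 0.597), Zap70 by 0.48 with 1 rise of 5 T cell genes (1 adjusted over the list alone, adjusted p = 0.432), and Tagln by 0.56 and Sparc by 0.36 with 2 rises of 6 stromal genes (2 adjusted over the list alone, adjusted p = 0.316). In the fit with 1 weight per genotype the calls of Zap70, Tagln and Sparc ended, and 0 genes of the interferon, immediate early, T cell and stromal lists were called. Rises and falls were then 1 and 1 in each of glycolysis and cholesterol synthesis, and 1 and 0 in each of amino acid stress, the CDK inhibitor and G1 list, and hypermutation and repair. The lists of early B cells, NK cells and erythroid cells had under 5 kept members and were not tested, and median levels of NK and erythroid markers were 5.46 and 5.74 in wt+/mt+ and 5.55 and 5.60 in wt-/mt-.

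Whole chromosomes stood higher or lower in single wt-/mt- arrays. The SD of the chromosome medians was 0.184, 0.0871 and 0.137 in wt-/mt- replicates 1, 2 and 3, above all of 1000 shuffles of the chromosome labels in each (highest 0.0350, 0.0360 and 0.0420), and between 0.0096 and 0.0317 in the 9 other arrays. The SD also exceeded every shuffle in 7 of those 9 arrays, so the shuffles alone do not set wt-/mt- apart, and the size against the other arrays does. The chromosomes concerned differed between the wt-/mt- arrays. The lowest chromosome median was -0.71 over 414 genes in replicate 1 and -0.29 over 638 in replicate 3. In replicate 2 the highest was 0.25 over 565. Such shifts argue against a purely technical spread between the wt-/mt- arrays. Extra or lost chromosome copies may be present in the wt-/mt- cells as a hypothesis, with the lowest of the 3 values, 0.0871, beyond both bounds. Centring per chromosome lowered the median SD over genes in wt-/mt- from 0.261 to 0.251, still above the other genotypes.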
